A study of Mus musculus with 6 samples.

How the data were processed

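RNA from macrophages of 2 genotypes was sequenced in 6 samples, 3 control and 3 Morrbid cKO. Per the labels' protocols, marrow cells were cultured for 7 days at 37 °C and 5% CO2 with 50 ng/ml M-CSF, 20% fetal bovine serum and 1% penicillin and streptomycin. Per the same labels, RNA was extracted with TRIzol and sequenced by a nanoball method with probe-anchor synthesis. Groups were taken from the genotype given for each sample: mice with the flanked Morrbid gene alone were controls, and mice that also carried Lyz2-Cre were cKO.

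The authors deposited a comparison of the genotypes with 1 log2 fold change per gene, the ratio of Morrbid cKO over WT, per the file headers. WT was taken to mean the control group, whose mice had the flanked Morrbid gene without Cre. The authors' deposited table also held a p-value and a q-value for that ratio. Per the submitters' processing notes, Bowtie2, RSEM 1.3.1 and DESeq2 1.4.5 were used with the mouse build mm9, without a statement of the role or order of each. How lowly expressed genes were filtered, and how libraries were scaled, is not given in the sources used here. The table listed 16138 genes by Gene ID and symbol: 15979 of type mRNA, 92 pseudogenes, 57 long non-coding RNAs, 9 of another type and 1 small nucleolar RNA. The deposited q-values equalled a Benjamini-Hochberg adjustment of the deposited p-values over all genes within a relative difference of 0.00591. Among the genes, 2023 shared their log2 fold change and p-value with another gene, 407 of them at -0.98.

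The tests chosen before the data were examined needed values per library, which were not analysed here. The planned model fits for counts or normalized expression, the comparison of libraries by principal components and the per-sample values of Morrbid and Lyz2 were therefore replaced by tests that need only the deposited ratio and p-value. A gene was called changed at a q under 0.05. A signed normal statistic was computed from each two-sided p-value with the sign of its ratio. The standard error implied by the ratio and that statistic was used as a measure of precision in place of depth, which assumes a Wald-type test. Its median was 0.185 log2 units, with 0.0878 and 4.04 as the bounds that leave 5% of genes below and above. Gene lists fixed before the data were examined were tested with camera for pre-ranked statistics in limma 3.58.1, run in R 4.3.3, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 27 lists. The lists covered the Morrbid locus, apoptosis, inflammation, chemokines, alternative activation, interferon response, matrix proteases, macrophage identity, efferocytosis, lipid handling, antigen presentation, glycolysis, stress and NRF2 responses, cell cycle, immediate early genes, ribosomal proteins, Y-linked genes and markers of 8 other cell types. A list of mitochondrially encoded genes and Xist were not analysed here. Counts per list are given over all genes and adjusted over the list alone. Other steps used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

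Named genes followed a rule set in advance: Lyz2 and Bcl2l11, the 10 changed genes with the largest log2 fold change in each direction, up to 3 changed members of each list with the smallest p, and a few leading members of lists as values. Its conditions on expression level and on overlap between samples needed values per library and were not applied. Cebpa and Adgre1, and some members that did not pass, were named after their values were seen. A gene that the rule also picked is not reported here. Gene symbols were those of the authors' deposited table, and 16026 Gene IDs were found in the RefSeq annotation of assembly GRCm38. As that build differs from mm9, it was used only for names and for which genes neighbour each other, and no coordinates are given.

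The steps were tested on simulated data for the 16138 genes. With 200 genes changed by 0.5, 1 or 2 log2 units at the implied standard errors, 34.5%, 60.9% and 69.6% were recovered, and 4.83%, 4.32% and 5.18% of the calls were false. The interferon list, with 36 measured genes, was recovered in 99% of 100 simulated tables when shifted by 1 unit of the statistic. Without a shift, 1% of tables called any list. Other lists and smaller shifts were not simulated. The simulated genes varied independently of each other, so these rates do not cover lists whose genes vary together. Alternatives tried were a stricter q of 0.01 and a minimum log2 fold change of 1, both chosen in advance. Chosen after seeing the data were a Holm adjustment, mRNA genes alone, genes with an implied standard error of at most 1, and the omission of stromal and collagen genes. For the lists, a preset correlation of 0.05, ranks, the same limit on the standard error, and 10000 random lists matched on the standard error in 10 strata were also chosen after seeing the data.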

Results

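RNA sequencing was used to compare mouse bone marrow-derived macrophages of 2 genotypes. Such macrophages are grown from marrow progenitors in macrophage colony-stimulating factor (M-CSF). Morrbid is a long non-coding RNA expressed in myeloid cells, and its gene lies near Bcl2l11, which encodes the pro-apoptotic protein BIM. Control cells came from mice with a loxP-flanked Morrbid gene (3 samples). Knockout cells, called cKO here, came from mice that also carried Cre recombinase driven from the Lyz2 locus, which removes the flanked sequence in myeloid cells (3 samples). The series concerns vascular inflammation and aneurysm, and the comparison asks which macrophage transcripts differ between these genotypes. As only the knockout mice carried Cre, effects of Cre or of its place in the Lyz2 locus cannot be told apart from those of Morrbid loss. Values were 1 log2 fold change, 1 p-value and 1 q-value per gene for 16138 genes, as given in the authors' deposited table. No source used here says whether the samples of a genotype came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Values per library were not analysed here, and the depth of each library is unknown.

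The first comparison concerns the genes that tie the libraries to their genotype. Lyz2 (Gene ID 17105), which encodes lysozyme and whose locus drives Cre in these mice, was lower in cKO, with a log2 fold change of -0.85 and q = 4.6e-06 in the authors' deposited table. That is 0.555 times the control level. Lyz1, the neighbouring and nearly identical lysozyme gene, was also lower, at -0.76 with q = 0.00026 in the authors' deposited table. Reads from these paralogs may have been split between them, so the separate values are uncertain. Bcl2l11 (Gene ID 12125) had a log2 fold change of -0.24 with q = 0.292 in the authors' deposited table and did not pass the threshold of 0.05. None of the 7 measured genes around the Morrbid locus passed (median log2 fold change -0.04), and their camera adjusted p was 0.762. Morrbid itself was not analysed here, so the deletion was not checked at its own transcript.

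Across the genome, cKO macrophages differed from control macrophages in 278 of 16138 genes (1.72%) at the q threshold of 0.05 in the authors' deposited table, with 137 genes higher and 141 lower. The lower genes moved further. Their median log2 fold change was -0.85, against 0.59 for the higher genes, and 58 fell by at least 1 log2 unit while 36 rose by that much. At an unadjusted p under 0.05 there were 1426 genes, where chance alone would give about 806.9.

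The most extreme decreases among changed genes in the authors' deposited table were those of Gm16867 (Gene ID 100862085), a predicted gene, at -4.92 (q = 8.0e-18), and Ifi208 (Gene ID 100033459), at -4.66 (q = 5.33e-196). Ifi208 belongs to the interferon-inducible PYHIN family and was 25.2 times higher in control than in cKO, per the authors' deposited table. Bcat1, the cytosolic aminotransferase of branched-chain amino acids, was lower by a log2 fold change of -3.77 (q = 0.00241) in the authors' deposited table. The others reported here of the 10 strongest decreases among changed genes in the authors' deposited table ran from -2.33 to -2.20. They were Tnfrsf11b, the decoy receptor osteoprotegerin (-2.33, q = 0.0429), Col16a1, a collagen (-2.31, q = 0.0434), Cyr61, a matricellular protein (-2.23, q = 0.00111), and Msrb3, a methionine sulfoxide reductase (-2.23, q = 0.0447), in the authors' deposited table. Also in the authors' deposited table were Ptk7, a receptor-like pseudokinase, at -2.22 (q = 0.0110), and Fkbp10, a collagen chaperone, at -2.20 (q = 0.00374). Beside these decreases, the 17 measured markers of fibroblasts and other stromal cells had a median log2 fold change of -1.59.

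The 10 strongest increases among changed genes began with Gm46221, a predicted gene, at 3.81 (q = 0.00286), and Slc13a3, a sodium-coupled dicarboxylate transporter, at 2.37 (q = 6.0e-08), in the authors' deposited table. Marco, a macrophage scavenger receptor that binds bacteria and particles, stood at 2.23 (q = 0.0485) and Rab4a, a small GTPase of endosome recycling, at 2.22 (q = 3.4e-12) in the authors' deposited table. Susd2 (2.16, q = 0.0363), Xlr3b (2.01, q = 0.0276) and H2-M2, a class Ib histocompatibility gene (1.97, q = 0.00286), followed in the authors' deposited table. Wdfy1, an endosomal protein with a FYVE domain, rose by a log2 fold change of 1.81 (q = 5.3e-38), Gm42102 by 1.80 (q = 1.3e-07) and Tarm1, an activating receptor of myeloid cells, by 1.71 (q = 0.0148), in the authors' deposited table. How far a fold change can be trusted depends on its precision, which differed widely between genes. The standard error implied by each ratio and its p-value had a median of 0.185 log2 units, and at that precision a change of about 0.62 log2 units was needed to pass. For 3731 genes (23.1%) it exceeded 1 log2 unit and none of these passed; at a standard error of 1, a change of about 3.33 log2 units was needed.

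**Figure D1:**
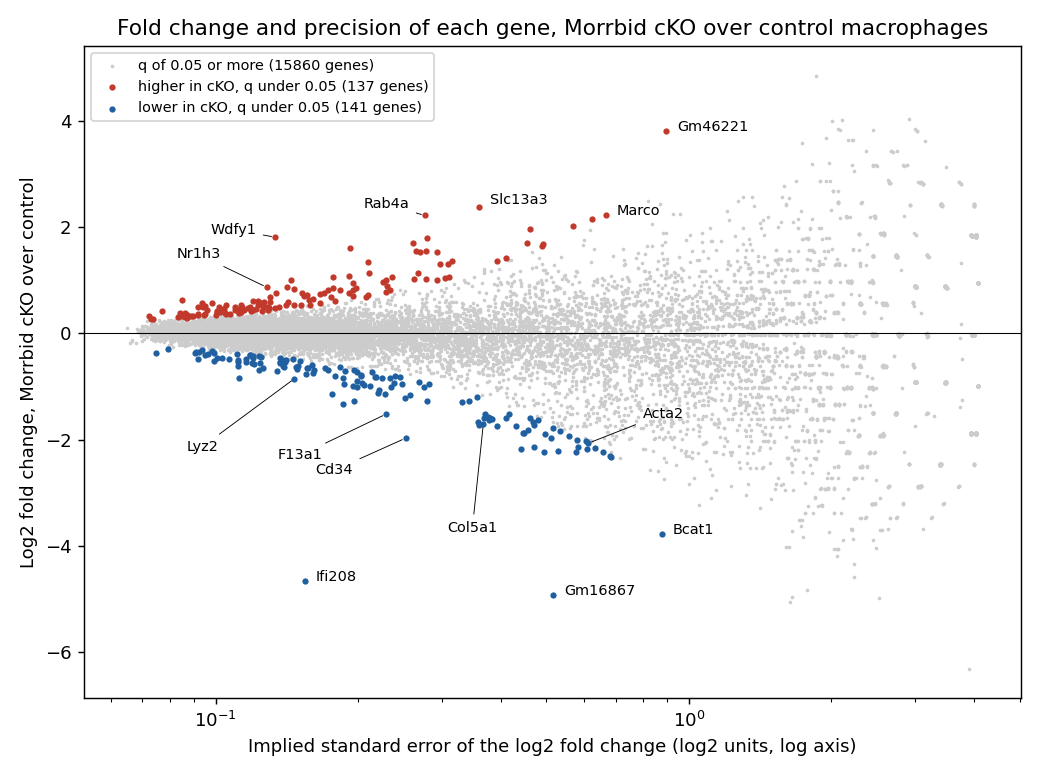
Each point is 1 of the 16138 genes, with the log2 fold change of Morrbid cKO over control on the vertical axis and the standard error implied by the deposited ratio and p-value, in log2 units on a log axis, on the horizontal axis. Red points are the 137 genes higher and blue points the 141 genes lower in cKO at q under 0.05, and Ifi208 at -4.66 stands apart from the other genes of similar precision.

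Gene lists fixed in advance grouped the genes by function and cell type. Of the 27 lists with measured members, 8 passed camera at an adjusted p under 0.05, with 3 higher and 5 lower in cKO. Camera compared the members of a list with all other genes at a preset inter-gene correlation of 0.01, and a correlation estimated from the libraries could not be had from 1 value per gene. Its p-values are therefore given with those at a preset correlation of 0.05 wherever the larger value ended a call. For lists whose members vary together more strongly than 0.05, both p-values are too small.

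The list of stromal markers was lower, although few of its members passed. Of 22 measured markers of fibroblasts, other stromal cells and endothelium, 2 fell, 1 rose and 19 did not pass; adjusted over the list alone, 13 fell and 1 rose. The list had a median of -1.34 and was lower by camera (adjusted p = 5.7e-08). Its 17 markers of fibroblasts and other stromal cells had a median of -1.59 with 16 below 0, whereas its 5 endothelial markers had a median of 0.60 with 2 below 0. Only 1 of these 5 passed the threshold, so the endothelial median is imprecise and does not show a rise of endothelial markers. Col5a1, a fibrillar collagen, was lower at -1.70 (q = 0.000815), and Acta2, smooth muscle actin, at -2.06 (q = 0.0458), in the authors' deposited table. Col1a1 (-1.68, q = 0.0679), Sparc (-1.73, q = 0.0676) and Tagln (-2.23, q = 0.0583) did not pass in the authors' deposited table. The member that rose was Pecam1, an adhesion molecule of endothelium and leukocytes, at 0.81 (q = 0.00156) in the authors' deposited table. Of 33 measured matrix proteases and their inhibitors, 3 fell and 1 rose; adjusted over the list alone, 8 fell and 1 rose. That list was lower (camera adjusted p = 0.00287, and 0.0731 at a correlation of 0.05), beside the fibroblast and stromal median of -1.59. Among its members, Spp1, osteopontin, was lower at -0.65 (q = 9.6e-05) and Mmp2, gelatinase A, at -1.30 (q = 0.00929), while Mmp14, a membrane-bound protease that activates pro-MMP2, was higher at 0.76 (q = 0.00127), in the authors' deposited table. Mmp12, macrophage elastase, stood at -0.62 (q = 0.0560) and Mmp9 at 1.10 (q = 0.530) in the authors' deposited table, and neither passed.

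Inflammatory genes were higher as a list. Of 29 measured cytokines and NF-kB targets, 3 rose, 0 fell and 26 did not pass; adjusted over the list alone, 8 rose. The camera adjusted p was 0.00112, and it was 0.0556 when ranks replaced the statistic. Those that rose were Tnfaip3, the deubiquitinase A20 that restrains NF-kB (0.40, q = 0.00815), Nfkbiz, a nuclear NF-kB cofactor (0.54, q = 0.0254), and Il1rn, the interleukin 1 receptor antagonist (0.82, q = 0.0287), in the authors' deposited table. Il1b (1.01, q = 0.368) and Tnf (0.40, q = 0.560) did not pass in the authors' deposited table. Of the 29 members, 18 had ratios above 0 and 11, several cytokines among them, had ratios below 0. Of 27 chemokines and chemokine receptors, 3 fell and 24 did not pass; adjusted over the list alone, 5 fell and 5 rose. They were the chemokine Ccl6 (-0.56, q = 0.000738) and the receptors Ccr1 (-0.94, q = 0.00871) and Cxcr4 (-0.72, q = 0.0119) in the authors' deposited table. The list median lay on the other side of 0, at 0.24, with a camera adjusted p of 0.629, and Ccl2 stood at 0.51 (q = 0.993) in the authors' deposited table. None of 36 interferon-stimulated genes passed, but 26 had ratios above 0, and the list was higher by a small amount (median 0.09, camera adjusted p = 0.0363, 0.218 at a correlation of 0.05, and 0.0639 over genes with an implied standard error of at most 1).

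Genes of lipid handling and of macrophage identity moved in part. Of 31 measured genes of cholesterol and lipid handling, 3 rose and 28 did not pass; adjusted over the list alone, 4 rose. They were Nr1h3, the oxysterol receptor LXR alpha (0.87, q = 1.7e-08), Pltp, the phospholipid transfer protein (0.60, q = 0.000155), and Lpl, lipoprotein lipase (0.43, q = 0.0104), in the authors' deposited table. The list median was only 0.05, the camera adjusted p was 0.00897, and it was 0.116 at a correlation of 0.05, 0.0808 with ranks and 0.283 by matched random lists. Abca1, a cholesterol exporter, stood at 0.36 (q = 0.178) in the authors' deposited table. Of 29 macrophage identity genes, 4 fell and 3 rose (camera adjusted p = 0.192); adjusted over the list alone, 6 fell and 4 rose. Besides Lyz2 and Lyz1, Apoe, apolipoprotein E, was lower at -0.54 (q = 0.00982) and Cebpa, a myeloid transcription factor, at -0.58 (q = 0.0202), while Adgre1, an adhesion receptor typical of mouse macrophages, was higher at 0.44 (q = 0.0104), in the authors' deposited table. Lpl and Marco were the other members that rose, and Csf1r, the M-CSF receptor, stood at -0.15 (q = 0.809) in the authors' deposited table. Of 25 genes of efferocytosis and complement, 1 fell (adjusted over the list alone, 4 fell and 3 rose), and of 20 genes of alternative activation, 1 fell (adjusted over the list alone, 1 fell and 1 rose). These were Itgb5, an integrin chain (-0.50, q = 0.0235), and Tgm2, transglutaminase 2 (-0.48, q = 0.00405), in the authors' deposited table, and the camera adjusted p-values of the lists were 0.226 and 0.682. Arg1 stood at -1.06 (q = 0.827) and Mrc1 at -0.27 (q = 0.720) in the authors' deposited table. None of 12 genes of antigen presentation by class II molecules passed (median -0.31, camera adjusted p = 0.0557).

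**Figure D2:**
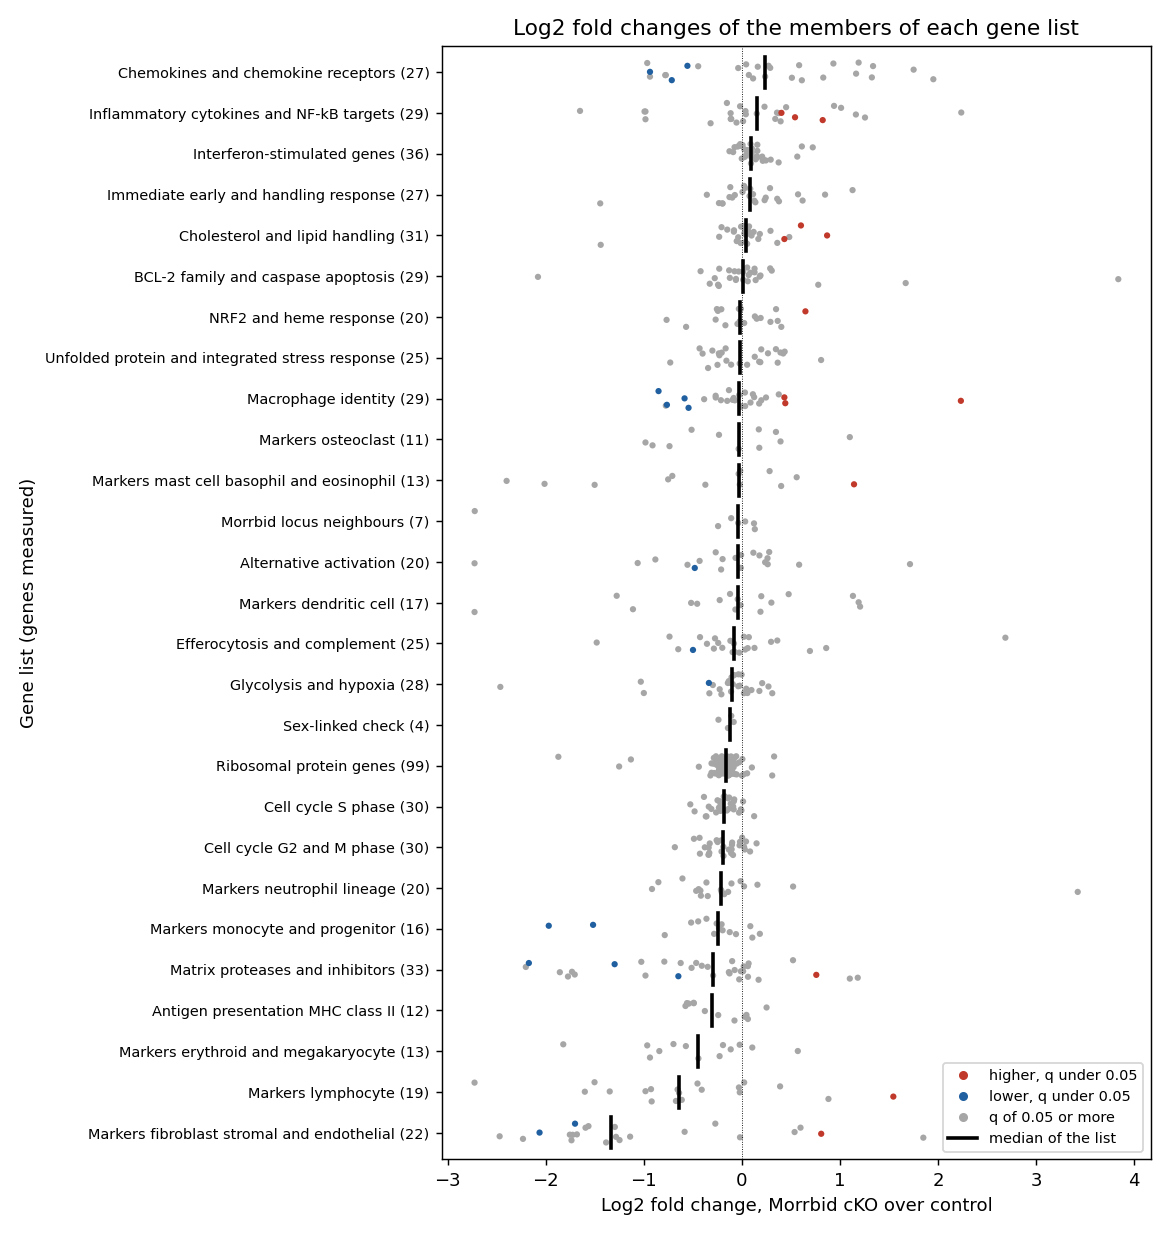
Each row is a gene list with the number of genes measured, each point is the log2 fold change of 1 member (Morrbid cKO over control), and the black bar is the median of the list. Red and blue points passed q under 0.05 as higher or lower, and the list of fibroblast, stromal and endothelial markers has the lowest median, at -1.34.

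Death, growth and stress genes showed few single changes. None of the 29 measured genes of the BCL-2 family and caspase apoptosis passed (camera adjusted p = 0.746), and Mcl1 stood at 0.18 (q = 0.886) and Bcl2 at -0.24 (q = 0.993) in the authors' deposited table. Ribosomal protein genes were shifted downwards by a small and even amount. Of 99 genes gathered by symbol, 92 had ratios below 0 and none passed, with a median of -0.16 and a camera adjusted p of 1.6e-12. The symbols also took in 10 genes, such as kinases of the Rps6k family, that are not ribosomal proteins, and without them the median was -0.16. None of 30 S phase genes passed, though 28 had ratios below 0 (median -0.18, camera adjusted p = 0.0527). Nor did any of 30 genes of G2 and M phase pass, with 24 below 0 (median -0.19, camera adjusted p = 0.0557). The proliferation marker Mki67 stood at -0.02 (q = 1.00) in the authors' deposited table. Of 28 glycolysis and hypoxia genes, 1 fell (adjusted over the list alone, 3 fell); the camera adjusted p was 0.0363, 0.205 at a correlation of 0.05, and 0.0609 over genes with an implied standard error of at most 1. That gene was P4ha1, a prolyl hydroxylase needed for collagen folding (-0.34, q = 0.0387 in the authors' deposited table), beside a median of -1.59 for the fibroblast and stromal markers. Sod2, mitochondrial superoxide dismutase, was higher at 0.65 (q = 0.00628) in the authors' deposited table and was the only one of 20 genes of the NRF2 and heme response to pass, also when adjusted over the list alone (camera adjusted p = 0.762). None of 25 genes of the unfolded protein and integrated stress response passed (camera adjusted p = 0.634), nor any of 27 immediate early and handling response genes (camera adjusted p = 0.203).

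Marker lists of other blood cell types had medians nearer 0 than the stromal list. An implied standard error of at most 1 was met by only 5 of 19 lymphocyte and 6 of 13 erythroid and megakaryocyte markers. The same held for 5 of 13 markers of mast cells, basophils and eosinophils, so these medians are imprecise. Of 16 markers of monocytes and progenitors, 2 fell, also when adjusted over the list alone, and the list was lower (median -0.25, camera adjusted p = 0.000313, and adjusted p = 0.239 by matched random lists). They were Cd34, a sialomucin of progenitor cells (-1.97, q = 1.4e-11), and F13a1, a coagulation factor chain made by monocytes (-1.52, q = 4.5e-08), in the authors' deposited table. Cd34 is also found on stromal and endothelial cells, whose markers had medians of -1.59 and 0.60, the latter over only 5 genes. Cd4 was higher at 1.54 (q = 4.0e-06) and Ccr3, the eotaxin receptor, at 1.14 (q = 2.8e-05), in the authors' deposited table. Cd4 was the only 1 of 19 lymphocyte markers to pass (list median -0.64, camera adjusted p = 0.466; adjusted over the list alone, 1 rose and 1 fell). Ccr3 was the only 1 of 13 markers of mast cells, basophils and eosinophils (median -0.03, camera adjusted p = 0.890), also when adjusted over the list alone. No marker passed among 20 of the neutrophil lineage (median -0.21, camera adjusted p = 0.1002), 11 of osteoclasts (median -0.03, camera adjusted p = 0.601), 17 of dendritic cells (median -0.04, camera adjusted p = 0.991) or 13 of the erythroid and megakaryocyte lineages (median -0.44, camera adjusted p = 0.1002). Adjusted over the list alone, 1 dendritic marker rose and 2 erythroid or megakaryocyte markers fell. The 4 measured Y-linked genes had log2 fold changes from -0.24 to -0.08 and none passed (camera adjusted p = 0.203).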

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

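The thresholds of q and fold change were planned, and every other alternative here was chosen after seeing the data. No paired analysis was possible because the authors' deposited table holds 1 ratio per gene and no values per library. For the same reason the planned refits with other tests, scalings and filters on low counts, the fits that leave out a sample, those with the replicate number as a block, camera with an estimated correlation, fry and other splits of the samples were not run, and depth limits could be judged only from the implied standard errors. At a q under 0.01, 165 genes were changed (84 higher, 81 lower), and 94 (36 higher, 58 lower) at an absolute log2 fold change of at least 1; both are stricter by construction. Lyz2, at -0.85, missed that minimum of 1 and passed under the other alternatives. A Holm adjustment, also stricter by construction, left 67 genes (36 higher, 31 lower). The count was 321 over genes with an implied standard error of at most 1, 273 over mRNA genes and 271 without 90 stromal and collagen genes. Against the 8 gene lists past the threshold, 4 passed at a preset correlation of 0.05 (larger assumed correlation), 9 with ranks, 6 with an implied standard error of at most 1 and 9 by matched random lists. Ranks and matched random lists each lost 2 of the 8 and gained 3 other lists. The stromal list (adjusted p from 6.4e-08 to 0.00135) and the ribosomal protein list (5.7e-16 to 0.00135) passed in each of the 4 alternatives, where 0.00135 comes from an unadjusted p of 0.0002, the smallest that 10000 random lists can give. None of the 4 alternatives allowed for members that vary together more strongly than a correlation of 0.05. How far these 2 lists would pass with such members was not tested. The monocyte and progenitor list passed 3 of 4 (0.00118 to 0.239, lost by matched random lists), as did the inflammatory list (0.00216 to 0.0556, lost with ranks) and the matrix protease list (0.00135 to 0.0731, lost at the larger correlation). The interferon (0.00614 to 0.218) and glycolysis (0.0304 to 0.205) lists passed 2 of 4, and the lipid list (0.0162 to 0.283) 1 of 4. Lists that missed the threshold but passed in an alternative were S phase with ranks and by matched random lists, G2 and M phase and neutrophil lineage with ranks, and chemokines and class II antigen presentation by matched random lists. No called list reversed. Of the 71 other named genes that passed, 25 calls were lost at a q under 0.01, 34 at the minimum fold change and 52 under Holm, each by construction, and none in the other alternatives that included them. Of the 20 named genes that did not pass, Tagln (adjusted p = 0.0448) and Mmp12 (0.0430) passed over genes with an implied standard error of at most 1, where fewer genes are tested, and none did in the other alternatives. The cause of each lost list call was not tested.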

Other observations

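The genes named in the next 2 paragraphs, the values restricted by precision, the collagen median, the larger preset correlation and the tests of other cell types, of PYHIN genes and of the surroundings of Ifi208 were chosen only after the results were seen.

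Regulators of the actin cytoskeleton and of cell adhesion were among the genes that rose. Src and Ptk2, kinases of focal adhesions, rose by log2 fold changes of 1.01 (q = 0.00171) and 0.95 (q = 0.000369) in the authors' deposited table. The same direction held for Rac2, a GTPase of leukocyte migration (0.50, q = 0.00815), Flna, an actin crosslinker (0.41, q = 0.00582), Vasp, an actin elongation factor (0.44, q = 0.0446), and Pfn1, profilin (0.31, q = 0.0254), in the authors' deposited table. A hypothesis is that actin regulators rose in general. A further list of 50 actin regulators, written before its values were looked at, left out the genes already seen to rise and so could hold none past the threshold as higher. It had 0 members past the threshold in either direction, 32 above 0 and a median log2 fold change of 0.10. Its camera p was 0.000466, and 0.0214 at a preset correlation of 0.05, which is consistent with a small upward shift of the list as a whole.

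Other changed genes lay outside the lists. Csf1, which encodes M-CSF, stood at -1.15 (q = 0.00127), the purinergic receptors P2ry13 and P2ry12 at -1.12 (q = 0.000131) and -0.64 (q = 0.00241), and Id3 and Smad7, targets of BMP and TGF-beta signalling, at -0.65 (q = 0.00405) and -0.83 (q = 0.0123), in the authors' deposited table. Nnt, a mitochondrial transhydrogenase gene that is partly deleted in the C57BL/6J strain, was higher at 1.01 (q = 5.36e-09) in the authors' deposited table.

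Stromal and matrix genes were the lowest list, and 4 of 39 collagen genes passed, with a collagen median of -1.14. If cKO cultures held fewer cells of a mesenchymal type, other genes of such cells would fall too: a further list, with no gene in a fixed list, had all 33 measured members below 0 and a median of -1.60 (95% bootstrap interval over genes -1.87 to -1.37). The list was written before its own values were looked at but after the changed genes had been seen, and holds none of these. Its 12 mesenchymal transcription factors had a median of -1.75, also -1.44 for the 4 with an implied standard error of at most 1 (Prrx1, Prrx2, Snai2 and Tead1). A lower TGF-beta response within macrophages alone predicted a median near 0 for factors that macrophages do not use, and the median was lower. Whether macrophages use these factors, or TGF-beta acts on them, was not tested. Smad7 and Id3, named above as targets of TGF-beta and BMP signalling, also fell (-0.83 and -0.65). That explanation therefore stays open. An equal fall in the share of every cell type other than macrophages is argued against by the neutrophil lineage. Over members with an implied standard error of at most 1, the bootstrap interval of its median was -0.42 to -0.16 (16 genes). That of the fibroblast markers was -1.73 to -1.28. In all, 4 of 5 other marker lists had intervals above the fibroblast interval, while the lymphocyte interval overlapped it. The erythroid and megakaryocyte (6 genes), mast cell (5) and lymphocyte (5) intervals rest on few genes. How far macrophages express the markers themselves, the dendritic ones (15 genes) included, was not tested. The intervals are over genes and do not measure the spread between samples. As all 5 medians were below 0, smaller falls of the other types stay open. Fewer mesenchymal cells may thus account for the pattern, but whether a genotype effect or the culture caused it, whether 1 control library carries it, and how far macrophages express these genes themselves stay open without values per library.

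Changed genes lay beside each other 11 times among 16026 placed genes, such as Col4a1 with Col4a2 and Tnfsf8 with Tnc, against a mean of 4.70 in 10000 random placements matched on precision (permutation test, one-sided p = 0.0068). Random placements do not allow for neighbours that are regulated together, so this excess alone does not tell its cause. All 11 pairs moved in the same direction, but how many would do so by chance was not computed. Pairs of the same family, taken as gene symbols that share their first 3 characters, were then left out. That left 8 pairs against a mean of 4.37 (same permutation test, one-sided p = 0.0685). By this count, chromosome segments of another strain in one genotype cannot be told apart from chance. Segments carried along with the Lyz2-Cre allele or the floxed Morrbid allele cannot be told apart from chance either. Around Lyz2, with Lyz2 and Lyz1 themselves left out, 3% of 100 tested genes (Kitl, Irak3 and Msrb3) were changed. The share elsewhere was 1.68% (one-sided Fisher's exact p = 0.238). Around Morrbid, 3% of 100 tested genes (Slc28a2, Gatm and Itpripl1) were changed, against 1.69% elsewhere (one-sided Fisher's exact p = 0.241). In simulated placements of the same 16026 genes, the test called 5% of 20 random tables, 39% of 100 tables with 4 planted pairs, 97% of 100 with 8 and 100% of 20 with 20. Nnt, higher at 1.01 in the authors' deposited table, goes with a strain difference at its own locus, which was not tested.

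Ifi208 fell by 4.66 on the log2 scale in the authors' deposited table, with the smallest q of all genes there. A general fall of the PYHIN gene cluster or of interferon signalling is argued against, because the other 12 measured PYHIN genes had a median of -0.010 and none passed, the 11 with an implied standard error of at most 1 ranged from -0.09 to 0.72, and the interferon list had a median of 0.09. A strain segment around Ifi208 cannot be told apart from chance, since 4% of its 100 neighbours (F11r, Kcnj10, Slamf8 and Adss) were changed against 1.68% elsewhere (one-sided Fisher's exact p = 0.0896). A variant confined to Ifi208 and an effect of Morrbid on this gene were not tested, and both stay open.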
